A study of Mus musculus with 24 samples.

How the data were processed

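The arrays were Illumina MouseRef-8 v2.0 bead arrays. Per the submitters' processing notes the arrays were read with GenomeStudio, whose version is not given in the sources used here. As deposited, the values are linear probe intensities in a non-normalized table of 25697 probes and normalized intensities of 18132 genes in the series matrix. The normalized intensities were made by the authors with quantile normalization and no background subtraction, which the values show: in 98.9% of ranks the sorted values differed between arrays by a coefficient of variation under 1%, and the array medians lay between 150.02 and 150.38. Of the gene-level values, 11677 (64.4%) matched a single probe of the non-normalized table within a root mean square of 0.01 on the log2 scale after a shift that depended on the level alone, and 6455 did not. Which probes stand behind each gene is not given in the sources used here.

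The plan fixed before the data were examined was to background-correct the non-normalized table with control probes and to filter on detection p-values. The tables used here hold no control probes, detection p-values or gene names for the probes, so the authors' normalized intensities were used instead. They were background-corrected with the normexp model of limma with an offset of 50 and taken to the log2 scale. The background was read from the mode of the normalized intensities, 137.3, with an SD of 0.0727 (log2) below the mode. Genes above 149.1, which is the mode plus 1.645 SD, on at least 6 arrays were tested. That left 10111 genes (55.8%) and put 8021 aside as too dim. For a group in which a gene was above this limit on none of the 6 arrays, the fold change is given as at least the ratio to the limit, both taken after the background step, which makes this ratio larger than that of the normalized intensities. A gene above it on only some arrays of the lower group keeps its computed fold change, which is then uncertain in size. In medium these were, among the genes named with a fold change, Cldn11 (2 of 6 arrays), Serpina3g and Nos2 (3), Clec9a (1), and Ly6a, Rnase2a, Cish and Dmkn (5). With IL-4 it was Cxcl10 (2), with IFN-gamma Htr2b (3), Cx3cr1 and Mpo (4), and Rnase2a, Ear2 and Cd79b (5), and with isoproterenol Serpina3g (2), Rnase2a (3) and Arg1 (4). Gene names were brought to current mouse symbols: 16965 matched, 2660 of them through a synonym, and 1167 kept the name in the file.

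The 2 arrays of each experiment and activator were averaged, which gave 12 values. A linear model with group and experiment was fitted with limma (moderated by empirical Bayes, prior degrees of freedom 4.96, residual 6), and 6 contrasts were tested with Benjamini-Hochberg adjustment over the 10111 genes. A gene was called changed at an adjusted p under 0.05. All p-values from this fit are two-sided. The groups, contrasts, averaging, threshold, lists of genes and the alternatives except 4 were chosen before the data were examined. The slide layout was read from the file header. Slide 1 holds all arrays of experiment 1, slide 2 those of experiment 2 except isoproterenol, slide 3 the isoproterenol arrays of experiment 2 and the media arrays of experiment 3, and slide 4 the rest of experiment 3. A fit with slide and experiment as blocks and tests within a slide, which use the single arrays, were added after the layout was seen. In the blocked fit the isoproterenol value of experiment 2 and the media value of experiment 3 each stand alone in their experiment and slide. They therefore have no weight in its contrasts. Alternatives were also tried for the background step, the dim-gene limit, probes in place of genes, unaveraged arrays with or without a block, the experiment term, the samples in the fit, the empirical Bayes step, a fold threshold of 1.5 and leaving out experiments.

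The 24 gene lists held 421 genes, of which 396 were in the normalized table and 311 were tested. They cover alternative and classical activation, interferon-inducible GTPases, MHC class II and class I presentation, type I interferon-stimulated genes, cAMP and CREB targets, beta-adrenergic signalling, NF-kB inflammation, cell cycle, cholesterol biosynthesis, glycolysis and hypoxia, scavenging and lipid handling, angiogenesis and tissue remodelling, NRF2, stress responses, heat shock, macrophage identity and markers of other cell types. Shifts of lists were tested with camera of limma at a preset correlation between genes of 0.01, then with the correlation estimated from the data, and with fry. For isoproterenol the list means were also compared with all 216 rearrangements of the media and isoproterenol arrays within experiments that keep 2 of each. Counts adjusted over the list alone use Benjamini-Hochberg adjustment within 1 list.

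Genes are named by a rule: for each activator against medium the 10 largest rises and falls among called genes with the same sign in the 3 experiments, up to 4 members of each list by the size of their log2 fold change, and a panel of known genes fixed beforehand for each activator. For the other 3 contrasts the 5 largest differences in each direction are named. Results of some genes the rule would name are not reported here. Genes named beyond the rule are said to be chosen after their values were seen.

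The position of each array was computed from genes called between IL-4 and IFN-gamma in the other 2 experiments, with weights from those experiments, and scaled so that the IFN-gamma mean of its own experiment is 0 and the IL-4 mean is 1. Genes called with isoproterenol were scored by their mean difference between IL-4 and IFN-gamma and compared with 10000 random lists drawn from 20 bins of expression. Overlaps were set against the product of the list sizes over the genes tested, against simulated unchanged groups sharing the media arrays, and against calls with the media arrays split between comparisons. The interaction of activator and experiment was tested with an F-test of limma on the 24 arrays.

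The steps were tested on simulated data with the size and spread of the real set. Of 100 genes changed 1.5-fold 99 were called, as were 99 of 100 changed 2-fold, with 12 calls among unchanged genes and 0 in a contrast without change. Simulated genes varied independently and had no slide effect, so these counts do not give the share of real changes that was found. A position difference of 0.1 was found as 0.0959. Computations used R 4.3.3 with limma 3.58.1, and plots used Python 3.11.15 with matplotlib 3.10.9. The planned search of promoter motifs needs a genome sequence and was not run.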

Results

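Expression of mouse genes was measured on 24 Illumina bead arrays, each hybridised with RNA of bone marrow-derived macrophages, which are macrophages grown in culture from the marrow precursors of female Balb/c mice. The cells had been kept for 24 h in medium alone or with 1 of 3 activators. Interleukin-4 (IL-4) served as the reference stimulus of alternative activation and interferon-gamma (IFN-gamma) as that of classical activation. Isoproterenol is a synthetic agonist of beta-adrenergic receptors, the receptors through which catecholamines of the sympathetic nervous system act. Per the series description, the study asked how beta-adrenergic stimulation changes macrophage transcription and where such cells lie between the IL-4 and IFN-gamma states. Each of the 4 groups held 6 arrays, 2 from each of 3 experiments. The 2 arrays were averaged before testing, so that n = 3 experiments per group. The labels do not say whether the 2 arrays came from separate cultures or animals, and the p-values measure only the spread between these samples, which may be technical. The median raw intensity per array lay between 134.6 and 172.2. After normalization, between 9230 and 9307 genes per array lay above the background limit, and 10111 genes were tested. The number of arrays limits the precision. Fold changes below come from background-adjusted log2 values, while means ± SD over the 3 experiments are normalized intensities without the background step.

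IL-4 raised the genes that define alternative activation, and its largest rises were far above its largest falls. Retnla, which encodes the secreted protein RELM-alpha, averaged 11324 ± 2993 (SD, n = 3) with IL-4 and was not above background in medium, and after the background step it was at least 137-fold higher (limma adjusted p = 2.8e-11). Arg1, the arginase that turns arginine into ornithine, was at least 30.1-fold higher (adjusted p = 9.3e-09), and Chil3, which encodes the chitinase-like protein Ym1, at least 5.20-fold higher (adjusted p = 3.3e-07). Among the other large rises were Rnase2a, an eosinophil-associated ribonuclease also called Ear11, with a log2 fold change of 6.38 ± 0.18 (SE), Il4i1, a secreted L-amino acid oxidase, with 4.02 ± 0.19, and Cish, a suppressor of cytokine signalling, with 3.53 ± 0.12. The tight junction gene Cldn11 was 13.4-fold higher and the lectin gene Mgl2 6.33-fold higher. Ear2 and EAR4 were 14.6-fold and 13.9-fold higher, but probes of this family of near-identical ribonucleases can read each other's transcripts, so these 2 values and that of Rnase2a are uncertain for the single gene. The largest falls were those of Tlr2, the receptor of bacterial lipopeptides, at 2.77-fold lower (adjusted p = 3.1e-07), and of the lipopolysaccharide co-receptor Cd14, at 2.38-fold lower (adjusted p = 2.9e-04). Gpr34, the prostaglandin D synthase gene Hpgds, the purinergic receptor gene P2ry13, Arap3 and the immunoglobulin receptor gene Fcgr1 were lower by 1.99-fold to 2.18-fold.

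In all, 407 genes were higher and 379 lower with IL-4 than in medium at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 50 of the higher and 8 of the lower genes changed at least 2-fold. All 786 had the same sign in each of the 3 experiments. Without experiment 1, 2 or 3 the count was 358, 419 or 467. It was 554 with the slide as a block, and within slide 1 and slide 2, which hold media and IL-4 arrays of experiments 1 and 2, it was 147 and 525.

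Of the 17 tested genes of the alternative activation list, fixed before the data were examined like the other lists, 15 rose with IL-4, or 16 when adjusted over the list alone. The mean log2 fold change was 2.13 (camera adjusted p = 1.2e-33, and adjusted p = 5.9e-04 with an estimated correlation). Beside the genes above, the mannose receptor gene Mrc1 rose 2.16-fold. Socs1, with a log2 difference of 0.33 ± 0.13, did not pass the test (adjusted p = 0.19), and the chemokine genes Ccl17 and Ccl22 were too dim to be tested. The list of genes for presentation on major histocompatibility complex (MHC) class II held 4 risers of 10, or 7 when adjusted over the list alone. They included H2-DMb1, a chaperone of peptide loading, at 2.37-fold, the class II transactivator gene Ciita at 1.82-fold and the invariant chain gene Cd74 at 1.74-fold. The list's camera adjusted p was 1.0e-05, but adjusted p = 0.31 with an estimated correlation. Type I interferon-stimulated genes went the other way, with 7 lower of 17, or 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.0e-05; adjusted p = 0.51 with an estimated correlation). Ifit3 was 2.32-fold lower, Rsad2 2.14-fold, Ifit2 1.86-fold and Oas2 1.79-fold. In these 4 genes the fall was smallest in experiment 1, for Rsad2 -0.33 against -1.32 and -1.64 in the other 2 experiments.

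Cholesterol biosynthesis genes shifted upward with IL-4. Of 20 tested, 7 rose, or 13 when adjusted over the list alone, among them Mvd at 1.52-fold, Cyp51 at 1.32-fold, the squalene epoxidase gene Sqle at 1.31-fold and Fdps at 1.29-fold (camera adjusted p = 7.5e-09; adjusted p = 0.13 with an estimated correlation). In the scavenging and lipid handling list 4 of 19 genes fell and 1 rose, or 6 and 2 when adjusted over the list alone (camera adjusted p = 0.048; adjusted p = 0.51 with an estimated correlation). The fallers were Gas6, a bridging ligand for apoptotic cells, at 1.87-fold, its receptor gene Axl at 1.75-fold, the scavenger receptor gene Stab1 at 1.65-fold and the fatty acid-binding protein gene Fabp5 at 1.48-fold. In the unfolded protein and integrated stress response list 2 of 16 rose, Pdia4 by 0.59 on the log2 scale and Creld2 by 0.45 (camera adjusted p = 0.016; adjusted p = 0.33 with an estimated correlation). No cell-cycle gene of 24 passed the test, and 23 had a lower mean (camera adjusted p = 0.0029; adjusted p = 0.75 with an estimated correlation). Taking the slide as a block, the mean difference of the cell-cycle list went from -0.30 to -0.05 and its camera adjusted p to 0.84, while the other 6 of these 7 lists stayed past the threshold. Other lists held single changed genes without passing camera. Angiogenesis and tissue remodelling had 5 higher and 2 lower of 20, NRF2 3 higher of 11, macrophage identity 3 higher and 2 lower of 11 with a median of 0.02 and a mean of -0.11, NF-kB 2 higher and 3 lower of 18, and beta-adrenergic signalling 4 lower of 17 with a median of 0.02 and a mean of -0.10. The classical activation list had a negative mean (-0.01) and an upward test, and the dendritic cell list a median of -0.04 and a mean of 0.44. Classical activation and interferon-inducible GTPase genes each had 1 higher and 2 lower, cAMP and CREB targets and glycolysis 1 in each direction, and MHC class I 1 higher of 15. Batf3, a transcription factor gene listed as a dendritic cell marker, rose 3.74-fold, Ccl7 1.86-fold, the cystine transporter gene Slc7a11 1.83-fold, Hbegf 1.77-fold and Igf1 1.69-fold, and Cx3cr1 was at least 1.76-fold lower.

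IFN-gamma changed more genes than any other activator here and gave the largest single changes. Ly6a, which encodes the surface protein Sca-1, averaged 31645 ± 1220 (SD, n = 3) against 159 ± 9.03 in medium, a 353-fold rise (limma adjusted p = 4.0e-13). Of the chemokine genes Cxcl9 and Cxcl10, whose products attract activated T cells, Cxcl9 rose to 23910 ± 3953 from 145 ± 4.52, above the background limit on 1 of 6 media arrays, so that the size of its rise is uncertain (adjusted p = 9.4e-13), and Cxcl10 rose 52.5-fold (adjusted p = 5.4e-10). Ccl5 rose 34.8-fold. Serpina3g rose 327-fold, Gbp2b 57.3-fold and Gbp3 33.8-fold, although probes of the Serpina3 and Gbp families can read related transcripts. The formyl peptide receptor gene Fpr2 rose 36.8-fold, Calhm6 35.8-fold and the interferon-inducible GTPase gene Igtp 34.6-fold. The largest falls were those of Lyzl4 at 13.7-fold, the serotonin receptor gene Htr2b at 8.48-fold, the lysosomal protease gene Ctsl at 8.00-fold, Cdkn1c, an inhibitor of cyclin-dependent kinases, at 7.06-fold, and Gas6 at 7.02-fold. Galnt9, LOC100048845, D12ERTD647E, Igfbp4 and Rhoj fell by factors of 5.96 to 6.94.

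With IFN-gamma 1750 genes were higher and 2612 lower than in medium, which is 43.1% of the genes tested, and 351 of the higher and 254 of the lower genes changed at least 2-fold. Of the 4362 genes, 4309 had the same sign in the 3 experiments. The count was 3999 with the slide as a block, and within slides 1 and 2 it was 2488 and 3370.

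The classical activation list had 16 of 18 genes higher with IFN-gamma, or 17 when adjusted over the list alone, with a mean log2 fold change of 2.79 (camera adjusted p = 6.9e-17; adjusted p = 0.03 with an estimated correlation). Beside the chemokines these were, among others, the transcription factor genes Batf2 at 20.3-fold and Irf1 at 6.18-fold, and Nos2, the inducible nitric oxide synthase, at 3.08-fold. All 10 tested interferon-inducible GTPase genes rose, with a mean of 3.89 (camera adjusted p = 7.4e-16; adjusted p = 0.03 with an estimated correlation), and Gbp5 was at least 22.7-fold higher. In the MHC class I list 14 of 15 rose, including the peptide transporter gene Tap1 at 9.57-fold, the transactivator gene Nlrc5 at 7.57-fold, Tapbpl at 4.78-fold and the immunoproteasome gene Psmb8 at 4.52-fold (camera adjusted p = 5.3e-15; adjusted p = 0.03 with an estimated correlation). In the MHC class II list 9 of 10 rose, with H2-DMb1 at 10.6-fold, Ciita at 9.14-fold, H2-Eb1 at 7.52-fold, H2-Ab1 at 4.61-fold and Cd74 at 2.63-fold (camera adjusted p = 4.2e-07; adjusted p = 0.11 with an estimated correlation). All 17 type I interferon-stimulated genes rose, led by Irf7 at 27.4-fold, Ifit2 at 23.2-fold, Oasl1 at 19.8-fold and Rsad2 at 14.8-fold (camera adjusted p = 8.3e-17; adjusted p = 0.11 with an estimated correlation).

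Genes of tissue remodelling fell with IFN-gamma. In the angiogenesis and tissue remodelling list 16 of 20 were lower and 1 higher, or 17 and 2 when adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.03 with an estimated correlation). They included Ctsl, the macrophage elastase gene Mmp12 at 5.72-fold, the metalloproteinase inhibitor gene Timp2 at 5.40-fold and the cathepsin K gene Ctsk at 3.72-fold. Cholesterol biosynthesis genes were lower in 14 of 20 and higher in 2, with Sqle at 2.58-fold, Cyp51 at 2.38-fold, Hsd17b7 at 2.13-fold and Stard4 at 1.71-fold lower (camera adjusted p = 0.0057; adjusted p = 0.26 with an estimated correlation). In the macrophage identity list 6 of 11 were lower and none higher, among them Cd14 at 1.99-fold, the lysosomal glycoprotein gene Cd68 at 1.84-fold, Cx3cr1 at 1.75-fold and the integrin gene Itgam at 1.57-fold (camera adjusted p = 0.024; adjusted p = 0.11 with an estimated correlation). Of the beta-adrenergic signalling components 9 of 17 were lower and 1 higher, with the receptor kinase gene Grk5 at 1.59-fold and the adenylyl cyclase genes Adcy9 and Adcy7 at 1.57-fold and 1.54-fold lower (camera adjusted p = 0.038; adjusted p = 0.12 with an estimated correlation). Glycolysis and hypoxia genes were higher in 11 of 17 and lower in 1, with the phosphofructokinase gene Pfkp at 3.73-fold and the hexokinase gene Hk1 at 1.72-fold higher (camera adjusted p = 0.0027; adjusted p = 0.33 with an estimated correlation). NF-kB inflammatory genes split into 11 risers and 5 fallers of 18, or 12 and 6 when adjusted over the list alone. Saa3 rose 20.6-fold, Icam1 6.05-fold and Tnf 3.60-fold, while Ccl3 fell 3.97-fold (camera adjusted p = 0.046; adjusted p = 0.53 with an estimated correlation). Unfolded protein and integrated stress response genes were higher in 8 of 16 and lower in 3, with the serine synthesis gene Psat1 at 2.34-fold and Chac1 at 2.27-fold higher and Herpud1 at 1.91-fold lower (camera adjusted p = 0.046; adjusted p = 0.26 with an estimated correlation). Scavenging genes went both ways, 5 higher and 7 lower of 19 (camera adjusted p = 0.64), as did alternative activation genes with 5 and 4 of 17, cAMP and CREB targets with 8 and 3 of 18, NRF2 genes with 2 and 3 of 11 and heat shock genes with 1 and 2 of 9, none past camera. The complement genes C1qa and C1qb rose 3.30-fold and 3.05-fold, and Stab1 fell 3.79-fold.

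**Figure D1:**
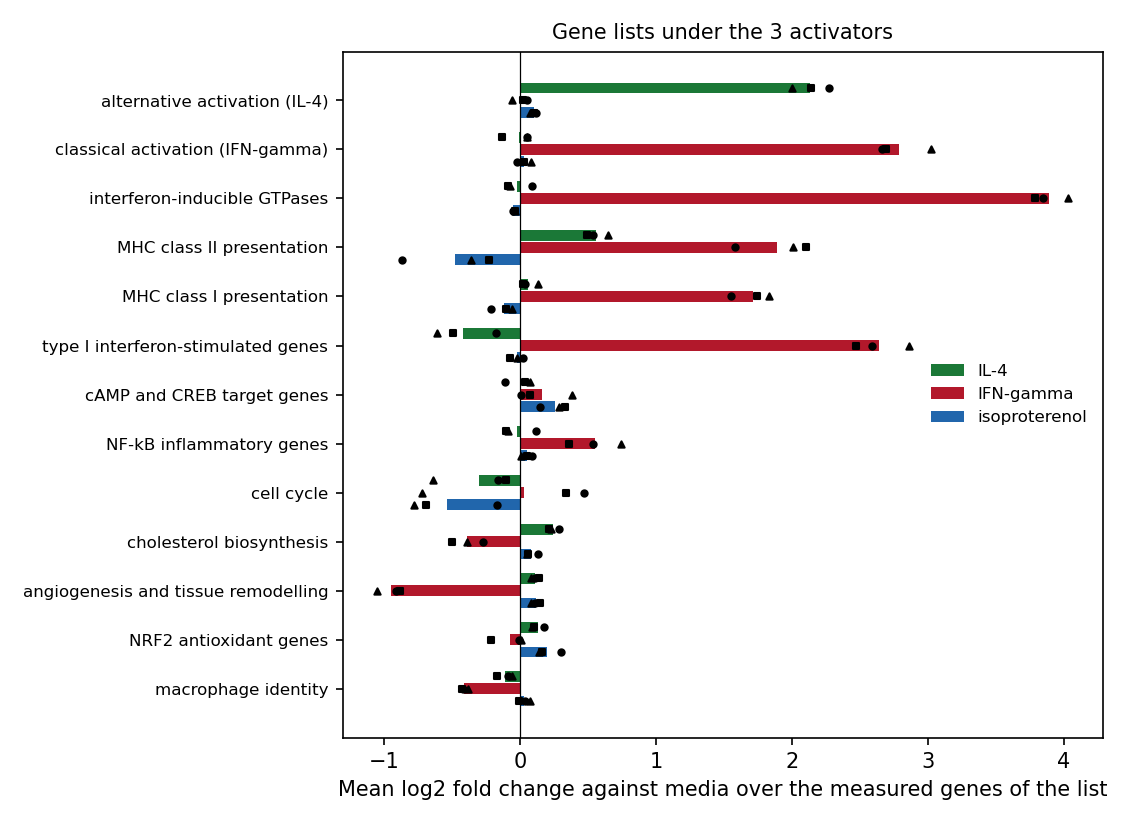
Mean log2 fold change against medium (horizontal axis) of the tested genes of 13 lists fixed beforehand, for IL-4, IFN-gamma and isoproterenol. Bars are means of the fitted log2 fold changes and the 3 symbols on each bar are experiments 1 (circle), 2 (square) and 3 (triangle). The bars of the interferon-inducible GTPase list reach 3.89 with IFN-gamma, and those of the cell-cycle list with IFN-gamma span experiments of opposite sign.

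The array of replicate 2 of the IFN-gamma group in experiment 1 stood apart from its partner. The correlation of log2 values between partner arrays was 0.977 for this pair and at least 0.996 for the others. On the 24-gene cell-cycle list this array had a mean log2 intensity of 9.21 against 7.34 in its partner, and on the type I interferon-stimulated list 9.35 against 10.42. The mean cell-cycle difference between IFN-gamma and medium was 0.47 in experiment 1, 0.34 in experiment 2 and -0.72 in experiment 3, and 1 gene passed the test in each direction (camera adjusted p = 0.47). The value of experiment 1 rested on this array, since its partner at 7.34 lay under the media arrays of experiment 1 at 7.79 and 7.82. The list mean over the 3 experiments was 0.03, and -0.28 without this array (camera adjusted p = 0.46). It was 0.29 with the slide as a block (camera adjusted p = 0.003), a fit that includes this array, and without that block the list gave adjusted p = 0.9 with an estimated correlation. Without this array the number of genes changed by IFN-gamma was 4396.

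Isoproterenol changed 129 genes against medium, 102 of them higher and 27 lower, which is 1.28% of the genes tested. The changes were of at most 2.80-fold, and 9 genes rose and none fell at least 2-fold. The largest rises were those of Cytip, a cytohesin-binding protein of leukocytes, Pf4, the chemokine platelet factor 4, Hilpda, a lipid droplet protein, and Ccl24, a chemokine for eosinophils. Cytip went from 2540 ± 954 to 6658 ± 390 normalized intensity (SD, n = 3), a 2.80-fold rise (limma adjusted p = 0.0043). Pf4 rose 2.58-fold (adjusted p = 0.0028), Hilpda 2.50-fold (adjusted p = 0.0015) and Ccl24 2.25-fold (adjusted p = 9.8e-04). Cav1, the main protein of caveolae, had the smallest adjusted p, 2.4e-05, with a log2 fold change of 1.07 ± 0.06 (SE) and values of 1.10, 1.01 and 1.08 in the 3 experiments. D330014H01RIK, Lyzl4, the collagen gene Col18a1 and Ppbp, another platelet chemokine gene, rose 2.03-fold to 2.24-fold. The immediate early gene Fos rose 1.88-fold (adjusted p = 9.8e-04).

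The largest falls with isoproterenol included MHC class II genes, whose probes can read related H2 transcripts. H2-Ea fell by 0.99 on the log2 scale (SE 0.19; adjusted p = 0.032), from 7208 ± 2965 to 3457 ± 681 normalized intensity, and H2-DMb1 fell by 0.94 (adjusted p = 0.045). In both, the difference was larger in experiment 1 (-1.62 and -1.51) than in experiments 2 and 3. LOC641240, an array name without a current symbol here, fell by 0.95. The chromatin protein gene Hmgb2 was 1.70-fold lower, Slamf9 1.70-fold, the extracellular glutathione peroxidase gene Gpx3 1.64-fold, Cdkn1c 1.53-fold, Mamdc2 1.46-fold, and the signalling genes Chn2 and Sla 1.45-fold.

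**Figure D2:**
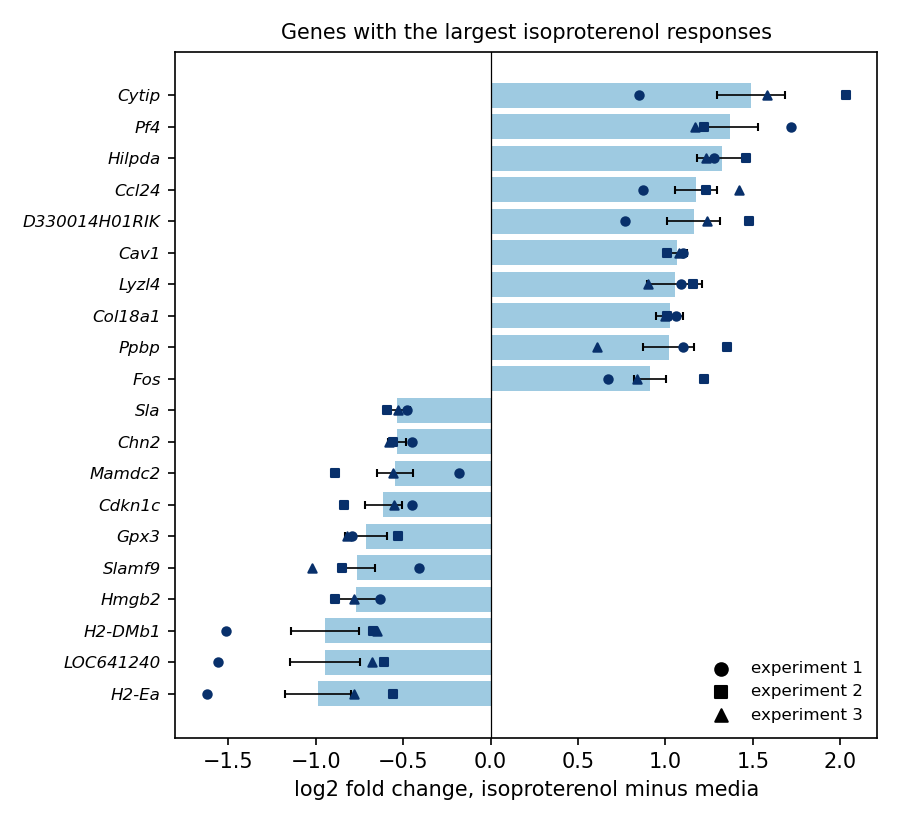
Log2 fold change of isoproterenol against medium (horizontal axis) for the 10 largest rises and 10 largest falls among genes past the test with the same sign in the 3 experiments. Bars are fitted values, whiskers ± 1 SE, and symbols the experiments. Cav1 and Col18a1 lie close to 1 in each experiment, while H2-Ea, LOC641240 and H2-DMb1 fell most in experiment 1.

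All 129 genes had the same sign in each experiment, but fewer genes were called when slides entered the fit or experiments were left out. Media and isoproterenol arrays share a slide in experiment 1 only, and with the slide as a block 5 genes were called by limma, Cav1, Col18a1, Pf4, Dmkn and Il1rn, of which Dmkn was chosen for naming after its value was seen. All 129 then kept their sign with an unadjusted p under 0.05, and their changes kept a median of 0.93 of their size while the median SE rose 1.26 times. In this blocked fit the isoproterenol arrays of experiment 2 and the media arrays of experiment 3 have no weight. The blocked difference rests on experiment 1 and on an indirect path through IL-4 and IFN-gamma in experiments 2 and 3. It is therefore not a slide correction of the result over the 3 experiments. Within slide 1 none was called, 627 of the 10111 tested genes had an unadjusted p under 0.05, and 97 of the 129 were among them. This fit took its spread from all arrays of experiment 1, including the IFN-gamma pair that stood apart. That pair widens the spread, so the absence of calls does not measure the isoproterenol effect within a slide. The 129 genes were picked on these same arrays, so their shared signs and low p-values are not a separate test. Without experiment 1, 2 or 3 the count was 38, 12 or 38.

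Genes named beforehand as targets of cyclic AMP and the transcription factor CREB, the pathway downstream of beta-adrenergic receptors, were higher with isoproterenol in 4 of 18 and lower in none, or higher in 9 when adjusted over the list alone. Fos, the phosphatase gene Dusp1 at 1.69-fold (adjusted p = 0.002) and Crem, an inducible repressor of this pathway, at 1.25-fold (adjusted p = 0.047) rose. The call of Crem was lost in 9 of 16 alternatives. The remaining called member, Cebpb, rose by 0.38 on the log2 scale (adjusted p = 0.036); it and Cxcl2 below lie outside the naming rule and were chosen after their values were seen. Thbs1 with 0.70 ± 0.23 and Vegfa with 0.50 ± 0.15 did not pass the test (adjusted p = 0.24 and 0.18), nor did Il10 with -0.11 ± 0.09 (adjusted p = 0.74). Nr4a1, Pde4b and Areg were too dim to be tested. The list had a camera adjusted p of 1.1e-06, adjusted p = 0.41 with an estimated correlation, and with the slide as a block its mean went from 0.26 to 0.14 (camera adjusted p = 0.024). Of 17 beta-adrenergic signalling components, Gnas, the stimulatory G protein gene, fell by 0.28 (adjusted p = 0.039, a call lost in 8 of 16 alternatives), 1 of 2 lower genes when adjusted over the list alone. The list as a whole did not pass camera (camera adjusted p = 1), with a median of 0.02 and a mean of -0.01.

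In the MHC class II list H2-DMb1 was the 1 called gene of 10, and 6 were lower when adjusted over the list alone. H2-Eb1 and H2-Ab1 had differences of -1.10 ± 0.24 and -1.07 ± 0.24 and Cd74 of -0.71 ± 0.20, which missed the threshold over all genes (adjusted p = 0.062, 0.065 and 0.14). The camera adjusted p was 5.8e-05, and adjusted p = 0.41 with an estimated correlation. The mean difference was -0.48, made of -0.87 in experiment 1, which is slide 1, and -0.23 and -0.36 in experiments 2 and 3. It was -0.68 with the slide as a block (camera adjusted p = 1.9e-06) and -0.29 without experiment 1 (camera adjusted p = 0.0031). All 15 MHC class I genes had lower means with none called, such as Psmb9 with -0.26 ± 0.08 and Psmb10 with -0.21 ± 0.06 (camera adjusted p = 4.0e-04; adjusted p = 0.41 with an estimated correlation; mean of -0.12, and of -0.19 with the slide as a block). Without experiment 1 their mean was -0.08 (camera adjusted p = 0.091). NRF2 antioxidant genes had a mean of 0.20, the same with the slide as a block, with none called over all genes and 6 higher over the list alone. They included Gsta3 with 0.56 ± 0.14 and Slc7a11 with 0.54 ± 0.14 (camera adjusted p = 2.2e-04; adjusted p = 0.41 with an estimated correlation). Cholesterol biosynthesis genes had a mean of 0.08 and none called (camera adjusted p = 0.047; adjusted p = 0.57 with an estimated correlation), and 0.07 with the slide as a block (camera adjusted p = 0.17). Without experiment 1 the NRF2 and cholesterol means were 0.15 and 0.05 (camera adjusted p = 0.068 and 0.32).

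All 24 tested cell-cycle genes had lower means with isoproterenol, none called over all genes and 12 over the list alone. Birc5 and Plk1, genes of mitosis, had differences of -1.09 ± 0.28 and -0.96 ± 0.28 (adjusted p = 0.11 and 0.16). The list mean of -0.54 (camera adjusted p = 2.5e-13; adjusted p = 0.43 with an estimated correlation, which was 0.88) was made of -0.17 in experiment 1, -0.69 in experiment 2 and -0.78 in experiment 3. In experiment 3 it was also -0.64 with IL-4 and -0.72 with IFN-gamma, since the media arrays, on slide 3, lay at 8.32 and 8.50 and the arrays of the other groups, on slide 4, between 7.63 and 7.79, so that the fall in this experiment is not particular to isoproterenol. Only experiment 1 has both groups on 1 slide, and with the slide as a block the mean was -0.09 (camera adjusted p = 0.25). The direct differences of -0.69 and -0.78 in experiments 2 and 3 do not enter that fit.

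**Figure D3:**
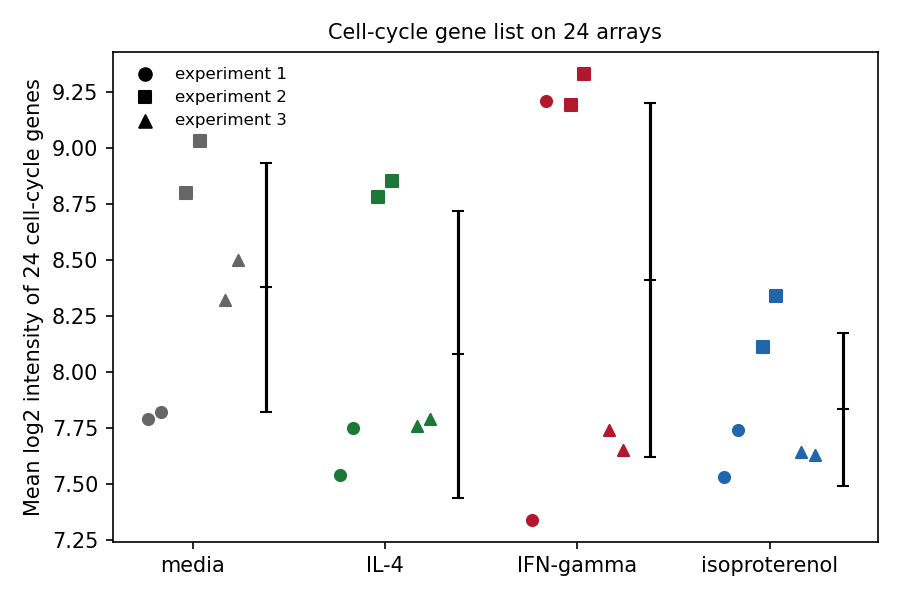
Mean log2 intensity of 24 cell-cycle genes (vertical axis) on each of the 24 arrays, by group, with symbols for the 3 experiments. Bars are the mean ± SD over 3 experiment means. In medium, IL-4 and isoproterenol the arrays of experiment 2 lie highest, and the IFN-gamma array of experiment 1, replicate 2, at 9.21 lies with those of experiment 2, apart from its partner at 7.34.

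Inflammatory genes moved both ways with isoproterenol. In the NF-kB list 3 of 18 rose and 1 fell, or 4 and 1 when adjusted over the list alone, with a median of -0.12 and a mean of 0.05 (camera adjusted p = 0.87). The risers were Il1rn, the interleukin-1 receptor antagonist, at 1.71-fold (adjusted p = 4.2e-04), and the neutrophil chemokine genes Cxcl1 at 1.61-fold and Cxcl2, by 0.43 on the log2 scale. The adhesion gene Icam1 was 1.39-fold lower (adjusted p = 0.0077). Tnf with -0.23 ± 0.14 and Il1b with 0.49 ± 0.28 did not pass (adjusted p = 0.61 and 0.56), and Il6 was too dim to be tested. In the angiogenesis and tissue remodelling list Ctsl rose 1.59-fold and Osm, oncostatin M, 1.47-fold, 2 of 20 (camera adjusted p = 0.12, and 0.033 with the slide as a block; adjusted p = 0.43 with an estimated correlation and no block). Stab1 rose 1.44-fold, 1 of 19 scavenging genes (camera adjusted p = 0.3), and Itgam 1.30-fold, 1 of 11 macrophage identity genes (camera adjusted p = 0.39). Among alternative activation genes Ccl24 rose, 1 of 17, or 2 when adjusted over the list alone, while Arg1, not above background in medium, did not pass (adjusted p = 0.55), nor did the list as a whole (camera adjusted p = 0.44; median -0.01, mean 0.10). Of the classical activation genes the costimulatory gene Cd86 rose 1.54-fold (adjusted p = 0.025) and Slamf8 was 1.18-fold lower (adjusted p = 0.046, a call lost in 11 of 16 alternatives), 1 in each direction of 18 (camera adjusted p = 0.94; median -0.01, mean 0.03). No member was called among 10 interferon-inducible GTPase genes, 17 type I interferon-stimulated genes, 17 glycolysis, 16 stress response and 9 heat shock genes. Median and mean differed in sign in the GTPase list (0.02 and -0.05), the stress response list (0.01 and -0.03, with the test upward) and the dendritic cell list (0.05 and -0.04).

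A second test of the isoproterenol lists rearranged the media and isoproterenol arrays within the experiments, in 216 ways. The list means of cell cycle, MHC class II, cAMP and CREB targets, NRF2, alternative activation and angiogenesis each gave the smallest possible two-sided p, 0.00926 (exact permutation test; 0.034 after adjustment over 22 lists). This test treats the 2 arrays of an experiment as independent and compares a list with no change, while camera, which the alternative activation and angiogenesis lists did not pass, compares it with other genes. Of the 22 lists large enough for camera, none passed with isoproterenol when the correlation was estimated.

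Lists of other cell types had no called gene with isoproterenol, few with IL-4 and more with IFN-gamma. This order is that of all tested genes, of which 1.28%, 7.77% and 43.14% were called, so it is not particular to these lists. Of the fibroblast and stromal list 1 gene of 10 was bright enough to test, Acta2, and of the erythroid list 2 of 9, and none was called with any activator. The lymphocyte, dendritic cell and mast cell, basophil and eosinophil lists had 4, 4 and 3 tested genes and no called gene with isoproterenol. With IFN-gamma, 2 of the 4 dendritic cell genes rose, Batf3 2.22-fold and Clec9a 1.20-fold. Of the 4 lymphocyte genes Lck rose 1.44-fold and Cd79b was 1.18-fold lower, with a median of -0.04 and a mean of 0.05 over the list, and of the 3 mast cell, basophil and eosinophil genes Gata2 was at least 1.24-fold lower. Neutrophil and granule genes had no called gene of 10 with isoproterenol, 1 lower with IL-4, S100a8 at 1.44-fold, and 2 higher and 5 lower with IFN-gamma, where S100a8 rose 2.72-fold and Mpo was 1.51-fold lower. Of the heat shock genes, Hsph1 rose by 0.59 on the log2 scale with IL-4 and was 1.39-fold lower with IFN-gamma.

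Set directly against each other, IL-4 and IFN-gamma differed in 4442 genes, 2557 higher with IL-4 and 1885 higher with IFN-gamma (limma). Higher with IL-4 were Retnla, by at least 137-fold (adjusted p = 4.8e-12), Rnase2a by 62.6-fold, Arg1 by at least 30.1-fold, Il4i1 by 24.6-fold and Ear2 by 22.7-fold. Higher with IFN-gamma were Ly6a and Cxcl9 (adjusted p = 3.6e-13 and 9.4e-13), each above background on 1 of 6 IL-4 arrays, Serpina3g by 206-fold, Cxcl10 by 62.6-fold and Fpr2 by 59.4-fold. Cholesterol biosynthesis genes differed in 15 of 20, 14 of them higher with IL-4, with a mean of 0.63 (camera adjusted p = 4.9e-06; adjusted p = 0.1 with an estimated correlation). A slide block gave 4556, and within slides 1, 2 and 4 it was 2198, 3490 and 3827.

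Isoproterenol and IL-4 differed in 1115 genes, 653 higher and 462 lower with isoproterenol. Apoc2, an apolipoprotein gene, was 3.12-fold higher with isoproterenol (adjusted p = 5.5e-06), Cd14 2.82-fold, Tlr2 2.80-fold, LOC100048845 2.65-fold and the lectin gene Clec4n 2.65-fold. Retnla was at least 137-fold lower, Rnase2a 86.8-fold, Arg1 28.5-fold, Il4i1 17.2-fold and EAR4 14.2-fold. The alternative activation list was lower in 14 of 17 (camera adjusted p = 6.8e-26; adjusted p = 0.0013 with an estimated correlation) and the MHC class II list in 7 of 10 (camera adjusted p = 5.6e-08; adjusted p = 0.23 with an estimated correlation). With a slide block 764 genes were called, 703 of them among the 1115, within slides 1 and 4 they were 208 and 768, and without experiment 1, 2 or 3 they were 519, 550 or 701.

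Isoproterenol and IFN-gamma differed in 4644 genes, 2708 higher and 1936 lower with isoproterenol. Lyzl4 was 28.5-fold higher with isoproterenol (adjusted p = 1.1e-09), Ctsl 12.7-fold, Ccl24 12.3-fold, LOC100048845 11.5-fold and Htr2b 9.49-fold. Cxcl9 was at least 286-fold lower, Ly6a 308-fold, Serpina3g 307-fold, Gbp2b 68.9-fold and Cxcl10 53.4-fold. In the angiogenesis and tissue remodelling list 18 of 20 genes were higher with isoproterenol (camera adjusted p = 3.0e-07; adjusted p = 0.038 with an estimated correlation). A slide block gave 4144, and within slides 1 and 4 it was 2386 and 3868.

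To place the isoproterenol arrays between the references, each array was projected on the line from the IFN-gamma mean (0) to the IL-4 mean (1) of its experiment, with genes and axis taken from the other 2 experiments (3318 to 3681 genes). Media lay at 0.859 ± 0.028 (SD, n = 3 experiments) and isoproterenol at 0.902 ± 0.014, closer to the IL-4 end of the axis by 0.043 ± 0.015. A higher position can come from less of the IFN-gamma pattern as well as from more of the IL-4 pattern. The difference was 0.026, 0.054 and 0.049 in experiments 1, 2 and 3. Rearranging arrays within experiments gave p = 0.00926 (exact permutation test, two-sided, 216 rearrangements, the smallest p possible). This test treats the 2 arrays of an experiment as independent. The IFN-gamma array that stood apart enters the zero point of experiment 1 and the axes used for experiments 2 and 3. Over the 3 experiments alone the exact sign-flip test cannot go below its p of 0.25. Only experiment 1, with the smallest difference, has media and isoproterenol on 1 slide.

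**Figure D4:**
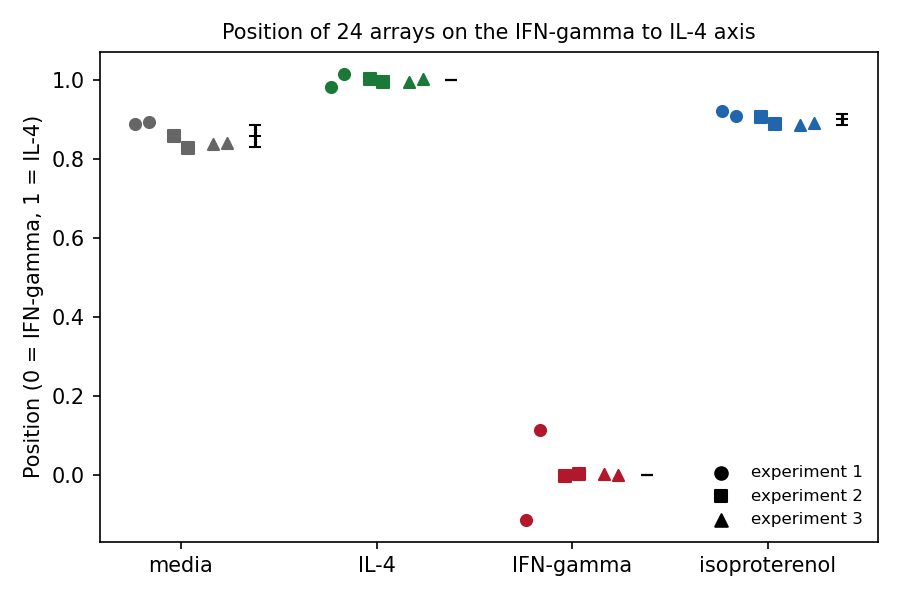
Position of each of the 24 arrays on the axis from IFN-gamma (0) to IL-4 (1), in units of the distance between these references (vertical axis), by group, with symbols for the 3 experiments. Bars are the mean ± SD over 3 experiment means. Media lie at 0.859 and isoproterenol at 0.902, and the 2 IFN-gamma arrays of experiment 1 lie at -0.114 and 0.114.

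The genes that isoproterenol raised were mostly those that IFN-gamma lowered. Over the 102 higher genes the mean log2 difference between IL-4 and IFN-gamma was 0.49, against 0.01 ± 0.07 (SD) in 10000 random lists matched on expression (permutation p = 0.0001, the smallest these lists can give), and 79 of the 102 were higher with IL-4 than with IFN-gamma. Against medium, these genes averaged 0.01 with IL-4 and -0.48 with IFN-gamma. Over the 27 lower genes the mean difference was -0.35 (permutation p = 0.014), with 0.33 for IFN-gamma against medium. The isoproterenol and IL-4 to IFN-gamma contrasts share no arrays. Both permutation p-values come from redrawing genes, with the array labels left in place. They treat genes as independent, so genes that vary together can make the spread of the random lists and these p-values too small.

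Of the genes raised by isoproterenol, 63 were lowered by IFN-gamma, where 26.3 would be shared by independent lists, and 15 were raised by it, against 17.7. Of the genes lowered, 13 were raised by IFN-gamma, against 4.7, and 9 were lowered, against 7.0. With IL-4, 20 were raised by both activators against 4.1 for independent lists, and 8 lowered by both against 1.0. Another 17 rose with isoproterenol and fell with IL-4, against 3.8, and 4 the reverse, against 1.1. Unchanged groups simulated against the same media arrays shared at most 0.01 genes on average. Such groups hold no true change, so this can not show how far shared media arrays raise the overlap of truly changed genes. With the media arrays split between the comparisons, the genes raised by isoproterenol and lowered by IFN-gamma were 27 and 36 in the 2 splits, against 8.5 and 12.4 for independent lists. Those raised by isoproterenol and IL-4 were 8 and 14, against 1.8 and 3.0, and those raised by isoproterenol and lowered by IL-4 were 11 and 16, against 1.8 and 2.8. Across genes, which are not independent replicates, log2 fold changes of isoproterenol and IFN-gamma had a correlation of -0.13 and a covariance of -0.0105, against a simulated covariance of 0.0034 from shared media arrays alone. For isoproterenol and IL-4 they were 0.14 and 0.0049. Shared media arrays alone gave a simulated correlation of 0.50. With the media arrays split, the correlations were 0.0666 and 0.078 with IL-4 (covariances 0.0024 and 0.0029) and -0.13 and -0.16 with IFN-gamma (covariances -0.0113 and -0.014).

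The effect of an activator differed between the experiments, by more than the 2 arrays of each experiment differed, in 9 genes over all activators, 1 gene for IL-4, 47 for IFN-gamma and none for isoproterenol (limma F-tests; 998 genes at an unadjusted p under 0.05 for isoproterenol). Without the IFN-gamma array that stood apart, which widens the spread between partner arrays, the counts were 889, 4, 960 and 88.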

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

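The tests of the 3 patterns below were chosen after the results were seen, while the comparison with other groupings of the arrays was planned before. Of 686 series of 6 arrays, 20 held an array far from the other 5 by a ratio of gap to range, where about 1 in 20 would by chance.

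The IFN-gamma array of experiment 1, replicate 2 (E1R2) stood apart from its partner in experiment 1. On 200 genes that separate experiments 1 and 2, scaled to 0 for experiment 1 and 1 for experiment 2, it lay at 1.49, next to the IFN-gamma arrays of experiment 2 at 1.47 and 1.60, while its partner lay at -0.02, which fits RNA of experiment 2 under an experiment 1 label. Its closest IFN-gamma array was replicate 1 of experiment 2, at a correlation of 0.9953. Its MHC class II list mean was 11.22, against 11.23 in both IFN-gamma arrays of experiment 2 and 11.78 in its partner. Its type I interferon list, however, lay 0.62 (log2) from the nearest IFN-gamma array of experiment 2, more than the largest gap of 0.43 between other partners, which speaks against a plain exchange of labels. Its cell-cycle list lay at least 1.39 above every other array of experiment 1, which argues against a mixture made of experiment 1 RNA alone. Mixtures that hold RNA of experiment 2 were not tested. The origin of this array therefore stays open. The same array was the odd one in IFN-gamma series of Batf3 (0.671; 8.87 against 9.24 to 9.42) and Irf7 (0.657; 11.13 against 12.14 to 12.67). It was also odd for Hbb-b1 (0.732; 7.03 against 7.19 to 7.25), but these values lie close to the background and say little.

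Cell-cycle genes had lower means with isoproterenol in each experiment, which may be a difference in proliferation, a slide difference or chance between cultures. Within slide 1, the only slide with both groups of 1 experiment, the list mean differed by -0.17, where the SD between partner arrays was 0.109, which can not tell a slide difference from a smaller effect. In experiment 3 the list was lower than in medium with all 3 treatments, by 0.64 to 0.78, with the media arrays of that experiment on slide 3 and the others on slide 4. The sign-flip p over 3 experiments was 0.25, the smallest it can give, so it says nothing about chance between cultures. Rearranging the arrays within experiments gave 0.00926 (exact permutation test; 0.034 after adjustment over 22 lists), which speaks against chance only if the 2 arrays of an experiment are independent.

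Pf4 and Ppbp, both genes of platelet granules, rose with isoproterenol. Of 9 other platelet or megakaryocyte markers in the table, 1 (Treml1, 493.7 against 502.4 in medium) lay above the limit on all isoproterenol arrays and 3 were bright enough to be tested, of which 0 were called higher. That leaves platelet or megakaryocyte RNA open, since the other markers may be too dim to show it. Within slide 1 the mean difference of Pf4 and Ppbp was 1.41 against an SD of 0.19, which a slide difference can not give. These genes were picked from results that include the slide 1 arrays, so its size may be overstated. With the slide as a block Pf4 stayed called and Ppbp did not.

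In the IL-4 group, replicate 1 of experiment 1 was the odd array for genes that interferon raises: Ifit2 (0.83), Ifit3 (0.777), Rsad2 (0.698; 9.89 against 8.16 to 8.68), Fpr2 (0.682) and Serpina3g (0.629), all higher there. Replicate 1 of experiment 3 was higher for Ly6a (0.841) and Cxcl9 (0.771), replicate 2 of experiment 2 for Prtn3 (0.892) and Mpo (0.646), and replicate 2 of experiment 1 for Klf1 (0.7). In the isoproterenol group Cxcl1 was lower in replicate 1 of experiment 3 (0.829) and Col18a1 in replicate 1 of experiment 1 (0.806). In medium, experiment 2, replicate 2 was higher for Cx3cr1 (0.79) and lower for Ndrg1 (0.758). Replicate 1 was lower for Irgm2 (0.693) and Prkar1a (0.667) and higher for Hbb-b1 (0.682), which lay close to the background.

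The effect of the activators differed between experiments in 9 genes over all activators, in 1 gene for IL-4, in 47 genes for IFN-gamma and in 0 for isoproterenol. Without the array that stood apart these counts were 889, 4, 960 and 88. Leaving it out narrows the spread between partner arrays, so these counts can not show whether that array explains the first ones.

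Each contrast was compared with 100 of the 462 ways to split its 12 arrays into 6 and 6, without averaging. In each of the 6 contrasts 1 split, the real one, gave as many genes. For isoproterenol against medium the real grouping gave 658 and the highest other 108, for IL-4 against medium 1807 and 309, and for IFN-gamma against medium 4449 and 2493. For IL-4 against IFN-gamma they were 4784 and 1860, for isoproterenol against IL-4 2248 and 0, and for isoproterenol against IFN-gamma 4898 and 1837. Arrays of an experiment resemble each other, so the splits are not independent cultures.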

How the results depend on the processing

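The slide block, leaving out the IFN-gamma array that stood apart, an offset of 16 and a polarity score from experiment 1 were chosen after the data were seen, and the other alternatives before. The filter on detection p-values was replaced by a stricter limit on dim genes (154.3), and the promoter motif search with its windows was not run. Quantile normalization without a background step and the deposited values on the log2 scale came to the same setting. Single probes in place of genes moved no count by 1.5 times. Except where said, the cause was not tested. Signal over background limits dim genes, and 8021 were not tested.

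No named call reversed its direction in 16 alternatives, and the single probes were not read for named genes. Of 94 named genes called with IFN-gamma 82 to 94 stayed called, of 64 with IL-4 43 to 64, and of 32 with isoproterenol 4 (slide block) to 32. The isoproterenol genes kept 7, 16 and 14 calls without experiment 2, 1 and 3, and 10 with no experiment term.

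Of genes changed by isoproterenol against medium, 129 in the report, there were 5 with the slide block, 36 with no experiment term, 45 at a change of at least 1.5-fold, and 83 with an offset of 16, of which 78 were among the 129. With the slide block, which compares isoproterenol and medium directly in experiment 1 only, the changes of the 129 genes kept a median of 0.93 of their size. These genes were picked on the same arrays, and the median SE rose 1.26 times. There were 196 with only the 2 groups in the fit. Without experiment 2 there were 12, and 38 without experiment 1 or without experiment 3, where fewer samples remain. Treating arrays as replicates raised the count to 373 unaveraged, 285 with a random block of experiment and activator, and 364 with the replicate block, whose replicate numbers do not pair arrays across groups.

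For IL-4 against medium (786) the count was 1340 unaveraged, 1300 with the replicate block, 447 with no experiment term and 222 at 1.5-fold or more. It was 358 to 467 without 1 experiment. For isoproterenol against IL-4 (1115) it was 1748 unaveraged, 1722 with the replicate block, 660 with no experiment term, 280 at 1.5-fold or more and 519 to 701 without 1 experiment. At 1.5-fold or more, IFN-gamma against medium gave 1316 (of 4362), IL-4 against IFN-gamma 1393 (of 4442) and isoproterenol against IFN-gamma 1483 (of 4644), and their other counts moved less than 1.5 times.

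The interaction of activator and experiment (9) was 34 with no background step and 889 without the array that stood apart. The position difference (0.043) lay between 0.0375 and 0.0516 when 1 experiment was left out, with an exact permutation p that can not go below 0.0556. The polarity kept its direction in the 10 alternatives run for it. Lower genes scored from -0.16 without experiment 1 to -0.5 without experiment 3, and higher genes from 0.39 with the random block to 0.71 without experiment 3. Where under 10 genes were called, as with the slide block and among lower genes without 1 experiment, the 100 genes of highest rank stood in for them.

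Genes shared by isoproterenol and IL-4 in the same direction (28) were 14 with the media arrays split, replicate 1 for isoproterenol, and 61 with the random block, and in opposite directions (21) 54 with the random block. With IFN-gamma the same direction (24) gave 9 with that split and 58 with the random block, and opposite directions (76) gave 33 and 42 with the 2 splits, where fewer arrays are used, and 162 with the random block.

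Of the gene lists that passed camera, with an estimated correlation 1 of 7 passed for IL-4, 4 of 12 for IFN-gamma, 0 of 6 for isoproterenol, 5 of 10 for IL-4 against IFN-gamma, 1 of 11 for isoproterenol against IL-4 and 4 of 11 for isoproterenol against IFN-gamma. With fry, which does not compare a list with other genes, 0 passed for isoproterenol, 16 for IL-4 against IFN-gamma and 17 for isoproterenol against IFN-gamma. The isoproterenol lists numbered 3 without experiment 1 and 7 without experiment 2, and isoproterenol against IL-4 had 7 with the slide block.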

Other observations

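The genes described in this part were chosen after their values were seen, as was the count of histone genes. Among genes outside the fixed lists, isoproterenol raised Cd28 (log2 fold change 0.85), C5ar1, the receptor of complement C5a (0.78), Dmkn (0.78), Pdpn (0.75), Cxcl14 (0.68) and the costimulatory ligand gene Cd80 (0.66). Cd80 and Cd86 both bind Cd28. It also raised Sphk1 (0.53), the messenger RNA decay factor gene Zfp36 (0.47) and Ada (0.41). Siglec1 (-0.49) fell. Of 10 tested histone H2B genes 5 were called higher, H2bc4 (0.45), H2bc14, H2bc9, H2bc7 and H2bc12, and none lower, but their sequences are close to identical and their probes can read each other's transcripts.

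Genes that isoproterenol shared with IL-4 included Cytip (1.49 with isoproterenol and 0.96 with IL-4), Ccl24 (1.17 and 1.47), Ier3 (0.66 and 1.53) and Cdkn1c (-0.61 and -0.47). IFN-gamma also raised Cytip (0.67) and lowered Cdkn1c (-2.82). Others went opposite ways, such as Apoc2 (0.71 and -0.93), Cd86 (0.62 and -0.66), Clec4n (0.59 and -0.82), Il1rn (0.77 and -0.40), Stab1 (0.53 and -0.73) and H2-DMb1 (-0.95 and 1.25). Ccl24 (-2.45), Lyzl4 (-3.78) and Ctsl (-3.00), all raised by isoproterenol, fell with IFN-gamma.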
